A study of Homo sapiens with 2 samples.

How the data were processed

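Guide abundance was measured in 2 libraries made from A549 cells of a pooled knockout screen, 1 from the brightest and 1 from the dimmest sorted fraction of a VENUS reporter. Groups were taken from the sample titles, which name the high and the low fluorescence gate. On average over the guides, at most 96.8 sorted cells per guide fell in each gate, from the numbers in the labels. Single guides can hold more or fewer.

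The table deposited by the authors holds whole-number read counts per guide and library, with the gene each guide targets, and the values were used as raw counts. Per the submitters' processing notes, cutadapt, MAGeCK and the human genome build hg38 were used, with versions not given in the sources used here. Trimming settings, mismatches allowed and guide sequences were not given in the sources used here either, so cut sites and off-target matches were not analysed. Reads of a guide that came from the same cell or PCR product cannot be told from independent cells, so that intervals and floors based on reads cover counting error only.

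Every guide was kept as listed, and a guide entered the ratios with at least 30 reads over both libraries, which left 74338 of 77441 guides (73346 against genes and 992 non-targeting). In the high gate 4401 guides had 0 reads and in the low gate 4347, with 2297 at 0 in both. Libraries were scaled by the median ratio to the geometric mean (size factors 1.007 and 0.993). The log2 ratio of the high to the low gate was taken with 0.5 counts added. For named genes with guides at 0 reads in a gate, the median was computed again with scaled counts below 3, including 0, set to 3. It is printed, as a bound, where the change was above 0.05 on the log2 scale, and the other such genes, MPHOSPH8 and SLC30A1 among them, keep the value with 0.5 counts added. The SDs of all genes with a guide at 0 depend on the counts added. A fold is the ratio of the summed scaled counts of a gene's guides.

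The labels name MAGeCK, so genes were tested by the same kind of robust rank aggregation (alpha 0.25), written in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Guides were ranked by a z value, the log2 ratio divided by an SD fitted on mean count over 50 bins. A p came from 5000000 random guide sets of the same size, so that 2e-07 is the smallest possible. In the main setting each guide of a random set was a rank position drawn evenly over the whole ranking. The text calls this a permutation test, although no guides were reassigned to genes. Each direction was tested on its own (one-sided), p was adjusted by the Benjamini-Hochberg method over the 18949 genes with at least 2 guides, and the threshold was 0.05. With 1 library per gate a count model has no residual degrees of freedom, and none was fitted. The p-values measure how guides of a gene rank among all guides of these 2 libraries and carry no error between sorts.

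Gene lists, 40 in all, the test, the settings and most alternatives were fixed before the data were examined. A list was described by the median of its gene log2 ratios and the percentile of this median among 10000 random lists matched on deciles of mean count. Percentiles describe these libraries and are not p-values. Members past the test were counted over all genes and adjusted over the list alone. Abundance was taken as the mean scaled count of a gene's guides relative to the median non-targeting guide. The agreement of guides against the same gene was tested with 1000 reassignments of guides to genes.

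Genes were named by a rule set beforehand. It takes METTL3, METTL14, EP300 and PAK2, the 12 genes of lowest p in each direction among those with at least 3 guides, and up to 4 members of each list, first those past the test and then those of largest absolute log2 ratio. The text names only some of the list members that this rule takes. Several further list members are named because they passed adjusted over the list alone, namely ATF7IP, DAXX, SETDB1, SENP1, TADA1, STK4 and KMT2B, and PPHLN1 because it passed over all genes, and these were chosen after their values were seen. Symbols are those of the table. Of 19114 gene names, 17852 matched a current RefSeq symbol and 1135 matched 1 gene through an older symbol. Coordinates are those of the gene in the RefSeq annotation of GRCh38, not of the guides.

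The script was tested on simulated data in 3 simulations of 18636 genes with reads that come in clumps, fitted to the zeros and the spread of the real olfactory receptor guides. Every guide of a changed gene was given the full fold. Of 259 calls, 6 were of unchanged genes (2.32%). Alternatives were other scalings, read minimums, added counts, guide rankings, alpha values, null sets, gene statistics and a threshold of 0.25. A restriction to guides read in both gates and a null from olfactory receptor guides were added after seeing the data. A further comparison of guide abundance is not reported here. Figures were drawn with matplotlib 3.10.9.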

Results

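A pooled CRISPR knockout screen was read out in A549, an established human lung adenocarcinoma line. The cells carried a doxycycline-inducible reporter in which METTL3 and METTL14, the core pair of the enzyme that writes N6-methyladenosine (m6A) on RNA, are each fused to a part of the fluorescent protein VENUS. The parts give light when they come together, so that fluorescence reports how much METTL3 and METTL14 associate. A genome-wide library of guide RNAs was delivered at 0.3 infectious units per cell. Cells were selected with puromycin at 5 µg/ml and, 5 days after selection and following 48 h of doxycycline at 2 µg/ml, were sorted from 1.5e8 cells. The brightest 5% (high gate) and the dimmest 5% (low gate) were kept, and 1 library of guides was sequenced from each. The deposited table counted 51571865 reads in the high gate and 51878459 in the low gate over 77441 guides, of which 76441 targeted 19114 genes and 1000 were non-targeting. A guide had a median of 477 reads in the high gate and 469 in the low gate. With 1 library per gate, no value below has a replicate check, and every test compares these 2 libraries, not the conditions. Errors are SDs over the guides of a gene.

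The first question was whether guides against METTL3 and METTL14, the genes of the reporter's parts, followed the sort. Guide sequences were not given, so whether these guides also cut the reporter fusions is not known. All 4 METTL3 guides were rarer in the high gate, with 87 reads against 1655 in the low gate, a 19.3-fold difference in the summed scaled counts. The median log2 ratio of the high to the low gate was −6.92 ± 4.36 (SD, n = 4 guides). It was −5.64 with the 2 guides without a read in the high gate set to 3 reads, so this median is a bound. METTL14 gave no such difference: its 3 guides with enough reads had 513 reads in the high gate and 190 in the low gate, and a median log2 ratio of 0.07 ± 4.68 (SD, n = 3 guides). METTL3 lies on chromosome 14 (21498138 to 21511340) and METTL14 on chromosome 4 (118685392 to 118715430) in GRCh38. METTL3 ranked 11 among the genes more abundant in the low gate but did not pass the robust rank aggregation test over all genes (p = 7.96e-05 from random guide sets, a permutation test, Benjamini-Hochberg adjusted p = 0.113). It passed this permutation test adjusted over the list alone (adjusted p = 0.000159, over both fusion partners). METTL14 was not past the test (p = 0.341 in the low direction, permutation test). The adjusted p of METTL3 ranged from 0.000379, with random sets of non-targeting guides, to 0.921, with only guides read in both gates.

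The main comparison asked which gene knockouts gave more cells in the brightest gate. Guides against 33 genes were more abundant in the high gate, and MPHOSPH8, FAM208A and MORC2, of the HUSH and SETDB1 list fixed beforehand, were among those of lowest p. MPHOSPH8, a chromatin reader of the HUSH silencing complex, had 45136 reads in the high gate against 1861 in the low gate (23.9-fold in scaled counts, median log2 ratio 4.81 ± 3.31, n = 4 guides). FAM208A (now TASOR), the HUSH scaffold, was 20.5-fold higher (4.51 ± 0.86), and MORC2, an ATPase that works with HUSH, 10.5-fold (4.03 ± 3.53, n = 4 guides each). SPIN1, a reader of methylated histone H3, was 16.6-fold higher (4.31 ± 0.90), and MORC3, a nuclear ATPase related to MORC2, 13-fold (3.76 ± 0.92). C15orf39 was 13-fold higher with close agreement of its guides (3.70 ± 0.29, n = 4 guides). These 6 genes shared the smallest p that the random guide sets allow, 2e-07 by this permutation test (adjusted p = 0.000632).

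OTUD5, a deubiquitinase, was 7.48-fold higher in the high gate (median log2 ratio 2.94 ± 0.60, n = 4 guides). TASP1, the protease that cleaves KMT2A, was 13.8-fold higher (3.79 ± 1.58), and TGIF1, a corepressor of the TGF-beta pathway, 5.76-fold (2.27 ± 0.30). SLC30A1, a zinc exporter of the cell membrane, was 19.1-fold higher over all 4 guides (4.13 ± 5.77). Of these, 3 were higher in the high gate, while the fourth had no read there. TRIM33, a ubiquitin ligase of chromatin, was 4.64-fold higher with 2 guides without a read in the low gate, so that its median of 5.48, with those set to 3 reads, is a bound. KIAA1551 (now RESF1), which acts with SETDB1 on retroelements, was 8.72-fold higher (4.58 ± 3.97). The adjusted p of these 6 genes lay between 0.00152 and 0.00284 in the rank aggregation test. Over all 33 genes the fold in summed counts ran from 3.04 to 32.6 with a median of 8.01. In 31 of them all guides were higher in the high gate, and 12 had a guide without a read in 1 of the gates. MPHOSPH8 lies on chromosome 13 (19633659 to 19673441), FAM208A on 3 (56620132 to 56683265), MORC2 on 22 (30925130 to 30968774), SPIN1 on 9 (88388444 to 88478694), MORC3 on 21 (36320197 to 36376632) and C15orf39 on 15 (75198889 to 75212169) in GRCh38. The count of 33 fell to 15 when guides were ranked by the log2 ratio alone and to 20 with the mean z value. It was 217 with random sets of non-targeting guides.

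**Figure D1:**
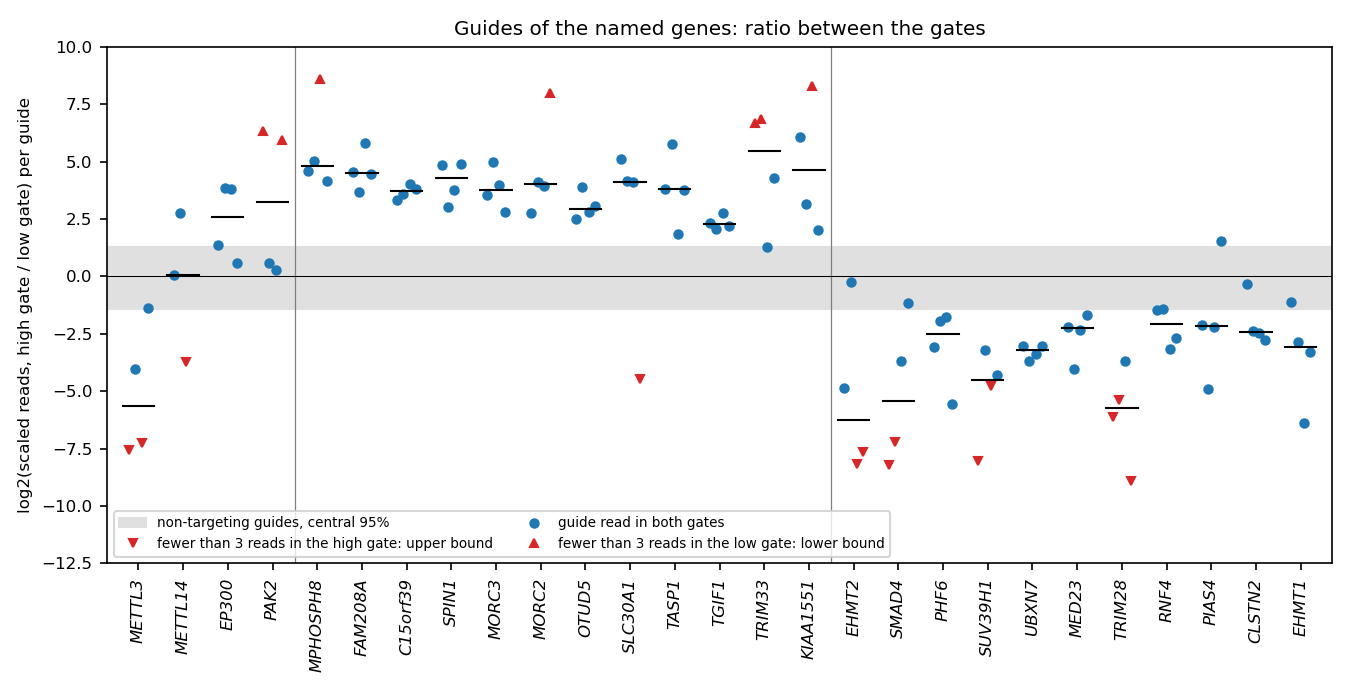
Each point is 1 guide, at the log2 ratio of its scaled reads in the high gate to those in the low gate, for the reporter genes, EP300, PAK2 and the genes of lowest p in each direction. Black bars are medians with scaled reads below 3 set to 3. Red triangles are bounds for guides with fewer than 3 reads in 1 gate. The grey band holds the central 95% of non-targeting guides (−1.42 to 1.29). All 4 guides of MPHOSPH8, FAM208A, C15orf39, SPIN1, MORC3, MORC2, OTUD5, TASP1, TGIF1 and KIAA1551 lie above the band. Those of PHF6, SUV39H1, UBXN7, MED23 and TRIM28 lie below it. The central 95% of olfactory receptor guides, at fewer reads, is wider (−3.45 to 3.41).

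In the opposite direction, guides against 7 genes were more abundant in the low gate. EHMT2, a methyltransferase of histone H3, had 583 reads in the high gate against 5586 in the low gate (9.72-fold, n = 4 guides, adjusted p = 0.00379 by the permutation test on guide ranks). SUV39H1, another histone H3 methyltransferase, had 687 against 7837 (11.6-fold, adjusted p = 0.00663 by the same permutation test, n = 4 guides). TRIM28, the corepressor that brings SETDB1 to chromatin, had 38 against 2253 (60.2-fold, n = 4 guides, adjusted p = 0.0471 by the same permutation test). Their median log2 ratios were −6.24, −4.53 and −5.75, with guides at 0 set to 3 reads, as was a TRIM28 guide with 1 read in the high gate. They are bounds because each gene has guides without a read in the high gate.

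The other genes past the test in the low gate were SMAD4, the shared mediator of TGF-beta signalling (5.05-fold, 1003 against 4996 reads), PHF6, a zinc finger protein of chromatin (5.05-fold, 1337 against 6653), UBXN7, a cofactor of the p97 segregase (8.91-fold, 810 against 7108), and MED23 of the Mediator complex (4.74-fold, 2153 against 10050). The 4 guides of UBXN7 agreed closely, with a median log2 ratio of −3.18 ± 0.31, and MED23 had −2.26 ± 1.02. PHF6 had −2.51 ± 1.74, and SMAD4 −5.45 with its guides at 0 set to 3 reads. Their adjusted p were 0.00663 for SMAD4 and PHF6, 0.00682 for UBXN7 and 0.0208 for MED23 in the rank aggregation test. All guides of all 7 genes were lower in the high gate. RNF4, a ubiquitin ligase that recognises SUMO chains (adjusted p = 0.110), and PIAS4, CLSTN2 and EHMT1, the partner of EHMT2 (adjusted p = 0.113 each), did not pass the permutation test. EHMT2 lies on chromosome 6 (31879759 to 31897698), SUV39H1 on X (48695554 to 48709016), TRIM28 on 19 (58544064 to 58550715) and UBXN7 on 3 (196347662 to 196432427) in GRCh38. The count of 7 fell to 3 with only guides read in both gates and rose to 188 with random sets of non-targeting guides.

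EP300, an acetyltransferase of histones and other proteins, and PAK2, a p21-activated kinase, were set apart because the study is thought to have followed them up, so their values here are not independent evidence. The labels do not state this, and it was not checked here. All 4 EP300 guides were higher in the high gate, with 4450 reads against 614 (7.14-fold, median log2 ratio 2.59 ± 1.68, n = 4 guides). EP300 ranked 98 in that direction and did not pass over all genes (p = 0.00172 by the permutation test on guide ranks, adjusted p = 0.332). Its adjusted p ranged from 0.0140, with random sets of non-targeting guides, to 0.593. All 4 PAK2 guides were also higher in the high gate, with 1845 reads against 1103, 1.65-fold in summed counts. The 2 PAK2 guides with the larger ratios had no read in the low gate, and its median log2 ratio was 3.26 with these set to 3 reads. PAK2 ranked 225 and did not pass (p = 0.00709 by the permutation test on guide ranks, adjusted p = 0.597). Its adjusted p ranged from 0.0518, with random sets of non-targeting guides, to 1 (p = 1 by the permutation test) with only guides read in both gates, which leaves out the 2 guides at 0. EP300 lies on chromosome 22 (41092592 to 41180077) and PAK2 on 3 (196739857 to 196832647) in GRCh38. Of 21 lysine acetyltransferases tested, 0 passed over all genes and 1, EP300, passed adjusted over the list alone. Members went both ways, with 4 at an unadjusted p under 0.05 by the permutation test in the high direction and 3 in the low. KAT7 was among the latter (−6.06 with its 2 guides at 0 in the high gate set to 3 reads, a bound). Of 13 p21-activated kinases and activators, 0 passed either way. Both lists were chosen with EP300 and PAK2 in mind.

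Of 40 gene lists fixed beforehand, the pair of reporter partners had a median log2 ratio of −3.43 (percentile 2.62). It was −2.79 with guides at 0 set to 3 reads (percentile 1.31), −1.43 with summed counts and −0.64 with only guides read in both gates. Among the other lists the HUSH and SETDB1 list stood farthest from 0. The 9 HUSH and SETDB1 genes had a median log2 ratio of 2.96, above all 10000 random lists matched on mean count (percentile 100), and 8 of the 9 were above 0. Of these 9, MPHOSPH8, FAM208A, MORC2 and PPHLN1 (4 genes) passed in the high gate over all genes, and TRIM28 (1 gene) passed in the low gate. Adjusted over the list alone, 7 passed in the high gate, the others being SETDB1 (0.20), ATF7IP (1.25), its nuclear partner, and DAXX (3.33), a histone chaperone, with median log2 ratios in brackets. PPHLN1, the HUSH subunit periphilin, was 9.32-fold higher (2.96 ± 1.50, n = 4 guides).

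The SUMO pathway, which attaches a small ubiquitin-like protein to its targets, had a median log2 ratio of 1.13 over 15 genes (percentile 100). PIAS2 (2.28), a SUMO ligase, passed over all genes. Adjusted over the list alone, 6 passed in the high gate, among them SAE1 (4.54) and UBA2 (3.10), the subunits of the activating enzyme, and SENP1 (2.78), a SUMO protease. In the low gate 2 passed in that way, the ligase PIAS4 (−2.15) and the protease SENP6 (−3.47 with its 2 guides at 0 set to 3 reads, a bound). The SUMO median was 0.57 with summed counts and 2.09 with the mean over guides. The SAGA and ATAC coactivators had a median of 0.98 over 20 genes (percentile 100), of which CCDC101 (now SGF29, 2.11) and TADA2B (1.70) passed over all genes and 7 passed adjusted over the list alone, TADA3 (1.87) and TADA1 (1.70) among them. Corepressor complexes of class I deacetylases had a median of 0.78 over 22 genes (percentile 99.98). Of these, 0 passed over all genes and 3 adjusted over the list alone, namely CHD4 (5.35 with its 3 guides at 0 in the low gate set to 3 reads, a bound), RCOR1 (2.20) and KDM1A (1.82). With summed counts the median of SAGA and ATAC was 0.54 and that of the corepressors 0.50. RNA polymerase II and its general factors had a median of 0.58 over 36 genes (percentile 99.91), with 0 past the test either way, and its median was 0.31 at 100 reads per guide and 0.92 with the mean over guides. Matching on mean count uses the reads of the same 2 libraries.

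Genes of the m6A pathway itself were also listed. The 6 further writer subunits had a median log2 ratio of −0.77 (percentile 1.38), with 5 of the 6 below 0. CBLL1 (−2.78 ± 2.15, n = 4 guides) was the 1 that passed adjusted over the list alone in the low gate, with 0 past over all genes. The 14 erasers and readers had a median of 0.73 (percentile 99.81), with 11 above 0. Adjusted over the list alone, the demethylase FTO (2.81) and the nuclear reader HNRNPA2B1 (2.89 with its 2 guides at 0 in the low gate set to 3 reads, a bound) passed in the high gate, and 0 passed over all genes. With the mean over guides the medians were −0.48 for the writer subunits and 0.42 for erasers and readers, and the difference between both lists was not tested. The 15 other RNA methyltransferases had a median of 0.09 (percentile 64.3), with 0 past over all genes. METTL5 (−2.51) passed adjusted over that list alone in the low gate.

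Single members of other lists passed over all genes. In the Hippo pathway NF2 (3.71), its membrane-proximal regulator, and AMOTL2 (2.81) passed in the high gate, and LATS2 (2.10) and STK4 (0.79), its kinases, also passed adjusted over the list alone, while the median of the 15 genes was 0.20 (percentile 86.8) and 0.45 with the mean over guides. In the TGF-beta pathway TGIF1 passed in the high gate and SMAD4 in the low gate, around a median of 0.08 over 17 genes, which was −0.17 with summed counts. CNOT4 (2.54) of the CCR4-NOT deadenylases, RNF7 (5.26) of the cullin ligases and CDK13 (3.67) of transcription elongation each passed in the high gate, with list medians of 0.18, 0.16 and −0.11, of which those of the cullin ligases (−0.04) and of elongation (0.01) changed sign at 100 reads per guide. The CCR4-NOT median was 0.03 without a minimum of reads. The Mediator list, with MED23 past the test, had a median of −0.01 over 28 genes, and 0.02 when scaled by the total count. The list named for methylation on lysines 4 and 36 of histone H3, not all of whose members are writers of these marks, had a median of −0.44 (percentile 2.31). It was −0.24 with only guides read in both gates. Of its 19 genes, 0 passed over all genes, and adjusted over the list alone 3 passed in the high gate, NSD1 (3.51) among them, and 2 in the low gate, MEN1 (−3.34) and KMT2B (−2.72). Of the 40 lists, 7 had a median above the central 95% of their random lists and 3 below it, where 2 would lie outside by chance, and 31 held no gene past the test. The PI3K and mTOR list (0.40) and the translation initiation list (−0.58) are among those outside and turned sign under other settings.

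**Figure D2:**
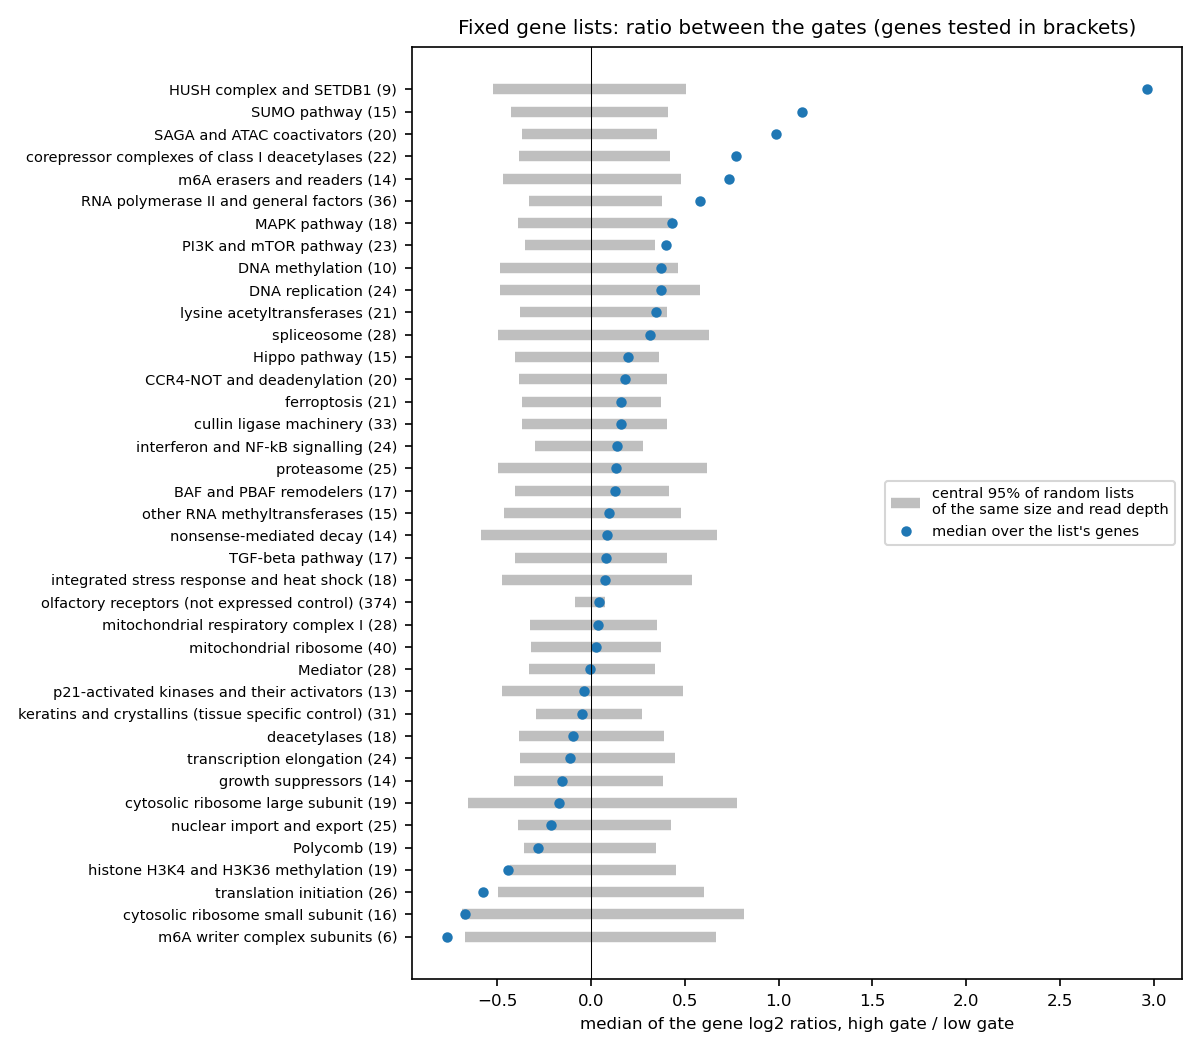
Each blue point is the median over the genes of a list of the log2 ratio of the high to the low gate, and grey bars span the central 95% of 10000 random lists of the same size and mean count. The list of the 2 reporter partners is left out. The HUSH and SETDB1 list stands at 2.96, and the SUMO, SAGA and ATAC lists at 1.13 and 0.98, while olfactory receptors lie at 0.04 (−0.01 with summed counts).

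Guides against genes that every cell needs were rare in both gates. Guides against the large subunit of the cytosolic ribosome had 1.71% of the reads of the median non-targeting guide, as the median over 31 genes, and those against the small subunit 2.90% over 24 genes. The spliceosome stood at 4.83%, translation initiation at 5.52%, the proteasome at 5.81%, DNA replication at 6.11%, RNA polymerase II and general factors at 10.3% and the mitochondrial ribosome at 13.8%. All of these were below all 10000 random lists of their size. Complex I of the respiratory chain stood at 20.7% (percentile 1.12). Guides against olfactory receptors, which lung cells do not use, stood at 33.2% over 374 genes, and keratins and crystallins at 34.5%, against 29.2% for all genes. Ratios between the gates rest on few reads for the rarest of these genes. Starting abundance in the plasmid library was not analysed here.

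**Figure D3:**
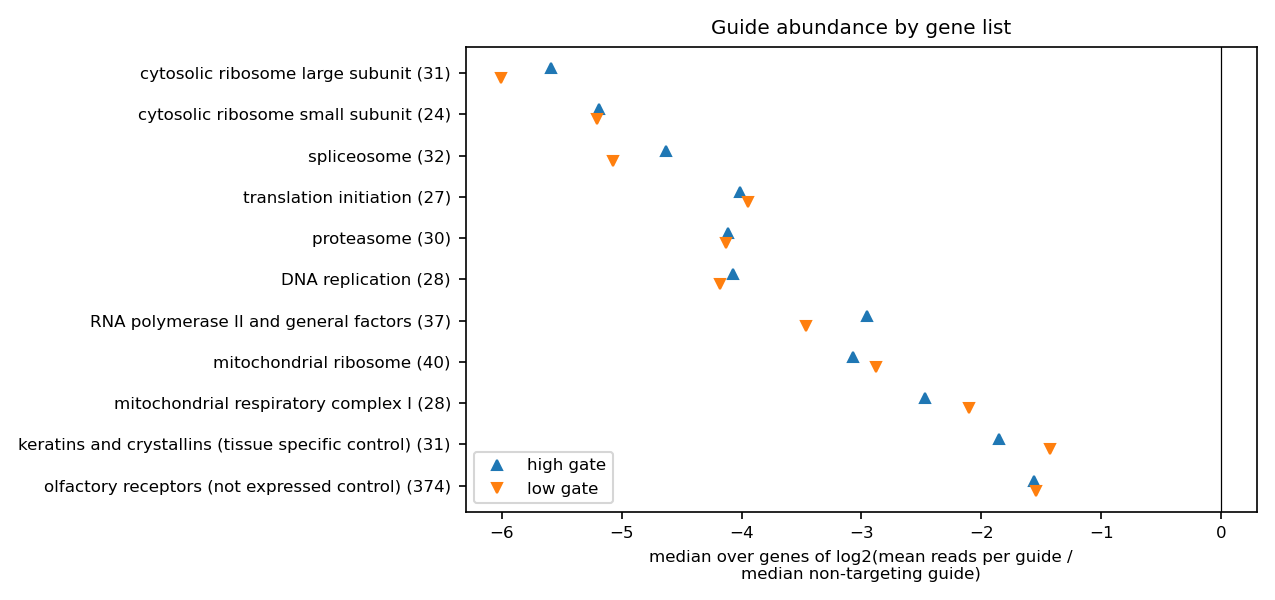
Points give the median over the genes of a list of log2 of the mean reads per guide relative to the median non-targeting guide, in the high gate (blue) and the low gate (orange), with the number of genes in brackets. Ribosomal genes lie lowest, near −5.59 and −6.00 for the large subunit, and olfactory receptors at −1.56 and −1.54.

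Control guides give the error behind these ratios. The 992 non-targeting guides with enough reads had a log2 ratio of −0.03 ± 0.69 (mean ± SD), where counting reads alone would give an SD of 0.05. Guides against olfactory receptors had an SD of 1.93 (n = 1478) at fewer reads, and guides against all genes 2.18. At like depth (700 to 1500 mean reads) olfactory receptor guides also spread more than non-targeting guides, with SDs of 0.94 and 0.72. In the olfactory receptor list 0 of 374 genes passed in either direction, with 12 and 19 at an unadjusted p under 0.05 in the high and low direction, and the median was 0.04 (percentile 88.7). By comparison, the keratin and crystallin list had −0.05 over 31 genes with 0 past the test. Guides of the same gene correlated weakly across genes, with Pearson's r = 0.033 and Spearman's rho = 0.038 over 106370 pairs, above the highest of 1000 reassignments of guides to genes (0.012, permutation p = 0.000999, the smallest they can give). Guides of a gene are not independent replicates of the sort. Over all 18949 genes tested, 1042 in the high direction and 1048 in the low direction had an unadjusted p under 0.05, or 5.50% and 5.53%. In simulated libraries with noise fitted to olfactory receptor guides, the test recovered 0% of genes changed 2-fold, 12.7% at 4-fold, 64.7% at 8-fold and 91.3% at 16-fold, while the genes past the test here went down to 3.04-fold. The simulation used 1 noise setting for all read depths and gave every guide of a changed gene the full fold. Recovery may therefore be lower in the real libraries.

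**Figure D4:**
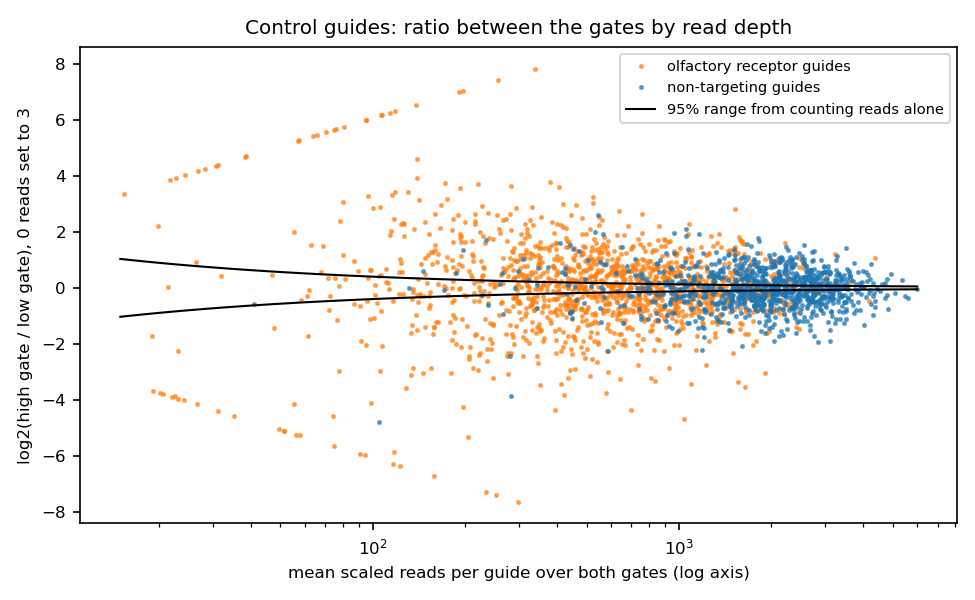
Each point is 1 control guide, with its mean scaled reads over both gates (log axis) against the log2 ratio of the high to the low gate. For olfactory receptor guides, scaled reads below 3 were set to 3. Black lines bound the 95% range that counting reads alone would give, and the non-targeting guides (blue, SD 0.69) and olfactory receptor guides (orange, SD 1.93) spread beyond it.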

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

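The restriction to guides read in both gates and the olfactory receptor null were chosen after seeing the data. No paired analysis was possible because each gate has 1 library, and for the same reason no library could be left out. Scaling by the total count or by the non-targeting guides left the counts at 33 and 7 genes and moved each list median by less than the SD of its random lists, though the Mediator median changed sign with the total count (−0.01 to 0.02). Of 13 alternatives, all called MPHOSPH8, FAM208A, MORC2, MORC3, SPIN1 and C15orf39 in the high gate, and 12 called EHMT2, SUV39H1, TRIM28 and UBXN7 in the low gate. Of the guides kept, 4.61% had 0 reads in 1 gate, and some of these had many reads in the other, such as a guide of MPHOSPH8 with 1162 reads against 0. The cause was not tested.

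The 33 genes of the high gate became 15 with guides ranked by the log2 ratio with 0.5 counts added (8 of the 33 kept), 15 with 10 counts added (13 kept), 20 with the mean z value (18 kept), 217 with the null from non-targeting guides (33 kept) and 73 at a threshold of 0.25. The 7 genes of the low gate became 4 with guides ranked by the log2 ratio with 10 counts added, 188 with the null from non-targeting guides, 15 without each gene's most extreme guide, 42 at a threshold of 0.25 and 3 with only guides read in both gates. By the permutation test with the null from non-targeting guides, EP300 (adjusted p = 0.0140) and METTL3 (adjusted p = 0.000379) passed. With the null from olfactory receptor guides neither passed the permutation test (adjusted p = 0.168 for EP300 and 0.0731 for METTL3). Non-targeting guides spread less between the gates (SD 0.69) than guides against genes (SD 2.18), at more reads. They also spread less than olfactory receptor guides in bins of like read depth. The SDs were 0.99 against 1.32 at 300 to 700 mean reads, 0.72 against 0.94 at 700 to 1500 and 0.63 against 0.94 at 1500 to 3000. Read depth alone therefore does not account for the difference between these control guides. The cause of these changes was not tested.

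Medians of 19 lists changed sign under at least 1 alternative, 17 of them inside the central 95% of their random lists. The 2 outside it were PI3K and mTOR, with a median log2 ratio of −0.21 at 100 reads per guide, −0.018 with the mean over guides and −0.045 with summed counts, and translation initiation, with 0.089 without a minimum of reads and 0.0017 with only guides read in both gates. Here too the cause was not tested.

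Other list medians moved by more than the width set for them. With summed counts they were −1.43 for the reporter partners, −1.13 for m6A writers, 0.50 for corepressors, 0.54 for SAGA and ATAC, −0.037 for DNA methylation, 0.57 for SUMO, −0.17 for TGF-beta, 0.70 for the spliceosome, −0.20 for translation initiation, −0.18 for complex I, −0.0052 for olfactory receptors and −0.25 for keratins and crystallins. With the mean over guides they were 0.35 for other RNA methyltransferases, 0.42 for m6A erasers and readers, 0.14 for deacetylases, 0.42 for p21-activated kinases, 2.09 for SUMO, 0.078 for nuclear transport, 0.45 for Hippo, −0.22 for the small ribosomal subunit, −0.28 for the proteasome and 0.92 for RNA polymerase II.

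At 100 reads per guide they were −0.0028 for DNA methylation, −0.042 for cullin ligases, 0.80 for SUMO, −0.54 for nuclear transport, 0.067 for the small ribosomal subunit, 0.31 for RNA polymerase II and 0.78 for DNA replication. Without a minimum they were 2.14 for HUSH and SETDB1, 0.13 for growth suppressors and 0.71 for DNA replication, and with 10 counts added −0.22 for translation initiation. With only guides read in both gates they were −0.64 for the reporter partners, −0.0028 for DNA methylation, −0.54 for nuclear transport, 0.25 and 0.067 for the large and small ribosomal subunits and 0.52 for the proteasome.

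Abundance relative to non-targeting guides moved in the high gate alone to −5.59 for the large ribosomal subunit, −4.63 for the spliceosome, −2.95 for RNA polymerase II, −3.07 for the mitochondrial ribosome and −2.47 for complex I, on the log2 scale. In the low gate alone it moved to −5.08 for the spliceosome, −3.46 for RNA polymerase II and −3.95 for translation initiation.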

Other observations

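Of the tests in this part, those of cutting by multicopy guides and of leaving out the most extreme guide of each called gene were set before their results were seen, and the others after. The genes in the next paragraph fall outside the naming rule, apart from SLC30A1, RNF7 and EHMT1, and were chosen after their values were seen.

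Some genes with related functions were read side by side, with no test of the grouping. MTF1, the transcription factor that responds to zinc, was 4.19-fold higher in the high gate (adjusted p = 0.00776 by the permutation test on guide ranks), as was the zinc exporter SLC30A1 (19.1-fold). ZCCHC8 of the nuclear exosome targeting complex was 3.38-fold higher (adjusted p = 0.0366, same permutation test), and ZFC3H1, which links the exosome to polyadenylated nuclear RNA, also passed. RNF7 is the RING subunit that pairs with CUL5, which was 4.81-fold higher (adjusted p = 0.276), and UBE2F, the conjugating enzyme that serves RNF7, was 3.76-fold higher (adjusted p = 0.654), so neither passed the permutation test. In the low gate SUV39H2, the paralog of SUV39H1, was 3.13-fold higher there (adjusted p = 0.200) and EHMT1, the partner of EHMT2, 7.87-fold (adjusted p = 0.113), and neither passed the permutation test.

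Guides differed between the gates by more than counting reads alone would give. The SD of non-targeting guides was 14.7 times that from counting. With 1 library per gate and on average at most 96.8 sorted cells per guide an excess was certain, so this is a description and excludes nothing. Few independent molecules per guide are a candidate explanation. The variance of the log ratio times mean reads should then be constant over read depth, and its highest bin was 1.93 times its lowest (95% bootstrap interval 1.55 to 2.88), which leaves this open. No biological explanation was tested.

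Non-targeting guides had 3.53 times the reads of olfactory receptor guides in the sorted cells. Loss of cells through cutting may contribute, since guides against 152 genes of near-identical multicopy families, which can cut at several sites, lay below olfactory receptor guides by a median log2 of −0.73 (SD of random lists 0.052). The share of each guide in the plasmid library cannot be told apart from this, because no plasmid library was analysed here.

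HUSH genes stood in the high gate while TRIM28, EHMT2 and SUV39H1, which also serve silent chromatin, stood in the low gate, a grouping made after the calls were seen. Leaving out the guide of largest absolute ratio of every member of the HUSH and SETDB1 list gave a median log2 ratio of 1.95 (SD of random lists 0.25, percentile 100), so 1 guide per gene does not account for that list. The called genes all kept an adjusted p under 0.05 by the permutation test without their most extreme guide (7 of 7, with 0.00370 for EHMT2 and 0.0111 for SUV39H1 and TRIM28). These genes were taken because they had passed a test that 1 guide can hardly pass. That result was therefore likely beforehand, and no conclusion is drawn from it. Several guides each carried by few cells also stay open. A sort that follows general transcription of the reporter would put guides against general factors in the low gate, and 0 of 3 such lists had a median below 0 by more than the SD of random lists. This cannot exclude that explanation. Guides against RNA polymerase II and general factors stood at only 10.3% of the median non-targeting guide. The Mediator list had 14 genes above 0 and 14 below. By the permutation test, 7 of its 28 genes had an unadjusted p under 0.05 in the low gate and 4 in the high gate. Release of the integrated reporter from silencing may explain the 4 HUSH list genes of the high gate as well as an effect on METTL3 and METTL14 contact, and these cannot be told apart because no reporter without the fusions was analysed here.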
